A study of Tachycineta bicolor with 14 samples.

How the data were processed

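Whole brains of 14 tree swallow (Tachycineta bicolor) embryos, a songbird that nests in cavities, were profiled by RNA sequencing at embryonic day 11, 7 from mothers breeding at high density and 7 from mothers breeding at low density. Per the labels' protocols, RNA was extracted with a combined DNA and RNA column kit, and polyA RNA was made into libraries with the xGen RNA library kit. The submitters' processing notes name fastp 0.20.1 and Salmon 1.9.0. The reference transcriptome, the rule that joined transcripts to genes and any filter on genes are not given in the sources used here. The deposited table holds 1 column of estimated counts per embryo over 13375 genes, and its values are those of unnormalized Salmon estimates, per the labels' tool list and the column totals. Of all values, 3.05% were not whole (tolerance 1e-06), 280 genes were 0 in all 14 embryos, and 175 others had counts identical to those of another gene. Each column name matched the description of 1 sample, which gave its group.

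Genes carry identifiers (tree_swallow and a number). Only 7 of them also carry gene names, and the file pairs no other identifier with a name. No genome or annotation was used here. The 35 gene lists fixed before the data were examined hold 1125 symbols, of which 0 matched a name in the file. No list could therefore be tested, so the list tests and the list scores per embryo were not made, and neither was the covariate built from sex-chromosome gene lists. No coordinates, chromosomes or functions of genes are given for the same reason. The rule for naming genes, fixed before the data were examined, took the 12 higher and 12 lower genes with symbols and the largest changes. Without symbols, the 2 higher and the 2 lower genes with the largest log2 fold change are named by identifier, among genes past the threshold with a mean of 1 CPM or more and one direction in all 14 fits that left out an embryo. This last condition removed 6 called genes, which the expression filter dropped from at least 1 of those fits, and 0 called genes reversed in any of them. The 6 tested genes with names are given in addition, a choice made after the file was seen. Of the 10 candidate genes that the rule asked for by symbol, none could be looked up.

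Estimated counts were rounded to whole numbers. Genes were kept with edgeR's filterByExpr (minimum count 10, minimum total 15), which left 10774 genes and dropped 2601. Libraries were scaled with TMM factors, and high density was compared with low density by edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3, robust fit, no covariate) with Benjamini-Hochberg adjustment at 0.05. Fold changes are log2, high minus low, and their standard errors are those implied by the F statistic. Values per embryo are CPM on TMM-scaled library sizes, or log2 CPM with a prior count of 2. The whole-transcriptome difference is the share of squared Euclidean distance between embryos that lies between groups. Principal components used the 500 most variable genes. The spread within a group is the mean distance of its embryos to their own centroid. Each of these was tested over all 3432 assignments of 7 embryos to a group, two-sided for differences. Tests of library totals, genes detected and the share taken by abundant genes were added after the file was seen, with the same exact permutation test.

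In counts simulated from the means, dispersions and library sizes of these 10774 genes, with 200 genes changed, the test of high against low density recovered 46 of 100 genes changed by 1 log2 unit and 89 of 100 changed by 2, and 7 of 142 calls were false. Genes were drawn independently, without differences between embryos that many genes share and without code prefixes. The share of false calls therefore need not hold for the real comparison. Alternatives set together with the design were DESeq2 1.42.0, limma-voom with quality weights (limma 3.58.1), RLE and upper-quartile factors, 2 other expression filters, a surrogate variable (sva 3.50.0), the letter prefix of the sample code, a looser threshold and leaving out each embryo. Leaving out high-density embryos 2 and 4, a filter of 5 CPM in 7 embryos, thinning all libraries to one total and 2 gene-derived covariates were added later. The labels do not say what the code prefix stands for, nor whether embryos came from separate nests, so p-values measure the spread between these samples. Permutations treat the 14 embryos as exchangeable, although 5 of the 6 prefixes occur in 1 density. Embryos are numbered within a group in accession order, and the numbers pair nothing.

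Totals ran from 3950422 to 6812901 estimated counts, at which 3 counts, the limit that a count of 0 allows, correspond to 0.759 and 0.440 CPM before TMM scaling. This limit covers counting error only.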

Results

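RNA sequencing measured polyA transcripts in whole brains of 14 tree swallow embryos at embryonic day 11, and the design asks whether brain expression differs with the density at which the mother bred. Breeding density varied naturally, per the series' design text. The 7 high-density libraries held 5685828 ± 1064544 estimated counts (SD, n = 7) and the 7 low-density libraries held 4994979 ± 869288 (SD, n = 7). This difference in totals was within the spread between embryos (exact two-sided permutation test, p = 0.204, adjusted p = 0.272 over 4 library measures). At least 1 count was found for 12187 ± 399 genes at high density and for 12164 ± 178 at low density (SD, n = 7 each; exact permutation p = 0.920, adjusted p = 0.920). High-density embryo 7 had the fewest genes detected, 11308.

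Most genes that differed between the densities were more abundant in brains of high-density embryos. Of 10774 genes tested, 615 (5.71%) passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, of which 546 were higher and 69 lower at high density. With a surrogate variable 0 genes passed, and the median change of the 615 in their called direction went from 1.41 to 0.82 log2 units. With the code prefix as a term, or without the prefix found in both densities, 0 genes passed as well. The share of higher genes was smaller at looser thresholds, with 994 higher and 321 lower (75.6% higher) at an adjusted p under 0.1 and 1611 of 2677 genes higher at an unadjusted p under 0.05. The higher genes were of low abundance at low density, with a median of 9.38 CPM against 29.8 CPM at high density, where the median over all tested genes was 27.8 and 28.8 CPM. Together they took 1.48 ± 0.21% of counts at low density and 4.01 ± 1.83% at high density (SD, n = 7 each). The 69 lower genes were more abundant, with medians of 75.9 CPM at low and 44.0 CPM at high density, and went from 0.978 ± 0.144% to 0.601 ± 0.156% of counts (SD, n = 7 each). These levels describe genes chosen for their difference in the same embryos.

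The higher genes also changed by more than the lower ones. Their median log2 fold change was 1.5, from 0.43 to 5.10, and 131 of the 546 rose by 4-fold or more. Among the lower genes the median was -0.81, from -0.47 to -2.41, and 1 of the 69 fell by 4-fold or more. The median log2 fold change over all tested genes was 0.01. In 140 genes the 7 high-density values lay entirely above or entirely below the 7 low-density values, where chance gives 0.0583% of genes, or 6.28. Of these 140 genes, 84 were above and 96 were among the 615. Genes vary together, so counts far above the chance value are not particular to density. A division picked from these data set high-density embryos 3 and 7 and low-density embryos 3, 4 and 6 against the rest. It had 22 genes entirely above and 98 entirely below, where chance gives 5.38 each way.

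**Figure D1:**
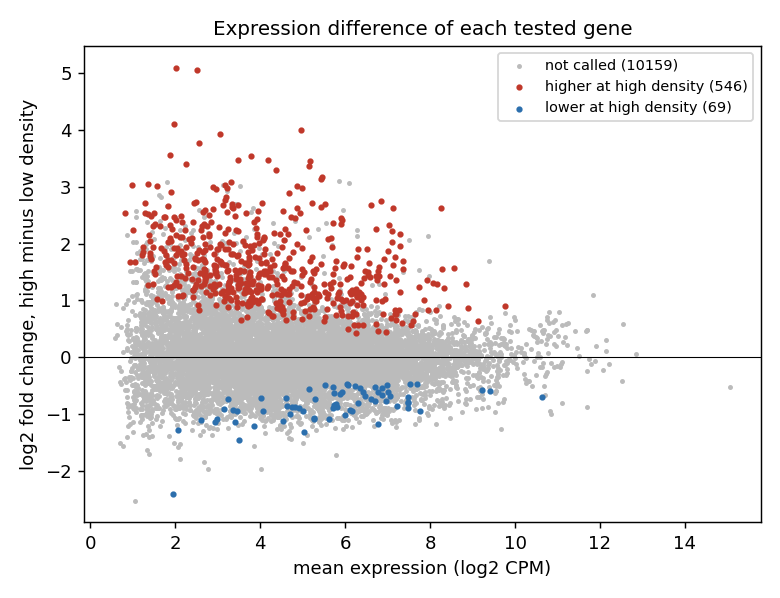
Log2 fold change of high minus low density (vertical axis) against mean expression in log2 CPM (horizontal axis) for each of the 10774 tested genes, with the 546 higher genes in red, the 69 lower genes in blue and genes that did not pass an adjusted p of 0.05 (edgeR) in grey. The red points reach a log2 fold change of 5.10 and the blue points -2.41.

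Genes with large changes are known here only by identifier, since the file does not pair them with names. The called gene with the largest log2 fold change, 5.10 ± 1.09 (SE; edgeR adjusted p = 0.0182), is not named, because the expression filter left it out of 4 of the 14 fits without 1 embryo. Of the genes with a value in all of these fits, the 2 that rose and the 2 that fell by most are given. tree_swallow008761 rose from 1.55 ± 0.85 CPM at low density to 53.6 ± 82.3 CPM at high density (SD, n = 7 each), with a log2 fold change of 5.06 ± 0.94 (SE) and an edgeR adjusted p of 0.0117. High-density embryo 2 held 235.8 CPM of it and high-density embryo 7 held 0, which allows up to 0.714 CPM before TMM scaling. tree_swallow005195 went from 2.08 ± 4.07 to 37.9 ± 36.0 CPM (SD, n = 7 each), a log2 fold change of 4.10 ± 1.10 (SE; edgeR adjusted p = 0.0401). Among the lower genes, tree_swallow000990 fell from 10.8 ± 10.5 to 2.06 ± 1.25 CPM (SD, n = 7 each), with a log2 fold change of -2.41 ± 0.66 (SE; edgeR adjusted p = 0.0425). Its level at low density was uneven, at 20.1 to 23.3 CPM in embryos 3, 4 and 7 and at 3.32 CPM or less in the other 4. tree_swallow016378 fell from 20.7 ± 9.7 to 7.54 ± 3.59 CPM (SD, n = 7 each), a log2 fold change of -1.47 ± 0.42 (SE; edgeR adjusted p = 0.0485). Each of these kept its direction in 18 of 18 other settings. For the 14 fits without 1 embryo, the rule that picked these genes had required it. The log2 fold change of tree_swallow008761 was 3.86 without high-density embryo 2, 3.39 without embryos 2 and 4 and 2.78 with a surrogate variable, the lowest of a range up to 5.29. That of tree_swallow005195 was 5.91 without low-density embryo 1 and 3.37 with a surrogate variable, the ends of its range. The other genes ranged from -2.75 to -2.08 (tree_swallow000990) and from -1.62 to -1.22 (tree_swallow016378). tree_swallow008761 passed the threshold in 17 of them, all but the fit with a surrogate variable (edgeR adjusted p = 0.384, the highest of a range from 1.33e-05). The other 3 passed in 6, 7 and 6 settings. tree_swallow005195 lost its call without any 1 of high-density embryos 1, 2, 4 and 6 or low-density embryos 2 to 7 (edgeR adjusted p from 0.0541 to 0.0878). tree_swallow000990 did so without any 1 of high-density embryos 1 to 4 or low-density embryos 2, 3, 4, 5 and 7 (0.0525 to 0.0899), and tree_swallow016378 without any 1 of high-density embryos 1, 2, 3, 4 and 6 or low-density embryos 2, 4, 5, 6 and 7 (0.0598 to 0.104). In the order given, these 3 genes had edgeR adjusted p-values of 0.627, 0.483 and 0.560 with a surrogate variable and of 0.185, 0.192 and 0.135 without high-density embryos 2 and 4.

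None of the 6 tested genes that carry names passed the threshold. Both entries named h3f3b and h3-3a, genes of the replication-independent histone H3.3, were among them. The more abundant one stood at 1563 ± 204 CPM at low and 1574 ± 404 CPM at high density (SD, n = 7 each; log2 fold change 0.01 ± 0.17 SE, edgeR adjusted p = 0.978), and its log2 fold change lay on either side of 0 in other settings, from -0.11 to 0.09. The less abundant one stood at 343 ± 80 and 299 ± 77 CPM (SD, n = 7 each; log2 fold change -0.20 ± 0.18 SE, edgeR adjusted p = 0.502). As histone and ribosomal protein genes have near-identical copies, whose reads could be split between entries, all of these values are uncertain. An entry named for histone H2B genes had a log2 fold change of -0.32 ± 0.34 (SE; edgeR adjusted p = 0.581), and one named for histone H4 genes 0.33 ± 0.38 (SE; edgeR adjusted p = 0.606), which was -0.07 without high-density embryo 7. An entry named for RPL9 pseudogenes, RPL9 being a protein of the large ribosomal subunit, was at 1899 ± 518 CPM at low and 2454 ± 929 CPM at high density (SD, n = 7 each; log2 fold change 0.37 ± 0.23 SE, edgeR adjusted p = 0.321). Tuba3a, an alpha-tubulin gene, was at 2.73 ± 1.28 and 5.11 ± 2.90 CPM (SD, n = 7 each). Its log2 fold change was 0.91 ± 0.39 (SE), with an edgeR adjusted p of 0.165 over all genes and of 0.198 over the 6 named genes alone. HSFY2, with 0 to 17 counts per embryo, was too low to test.

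High-density embryos did not carry the called genes equally. High-density embryo 2 lay above all 7 low-density embryos in 540 of the 546 higher genes, and embryo 4 in 535. Embryos 1, 3 and 6 did so in 514, 502 and 485 genes, embryo 5 in 285 and embryo 7 in 214. Among the 69 lower genes, embryo 2 lay below all low-density embryos in 68 and embryo 4 in 67, while embryo 5 did so in 40. In 257 of the higher genes and in 33 of the lower genes, embryos 2 and 4 held both extreme values of all 14 embryos. The genes were called with these same embryos, which favours values outside the low-density range. The same counts were not made over all tested genes, so they do not show a trait of the called genes.

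**Figure D2:**
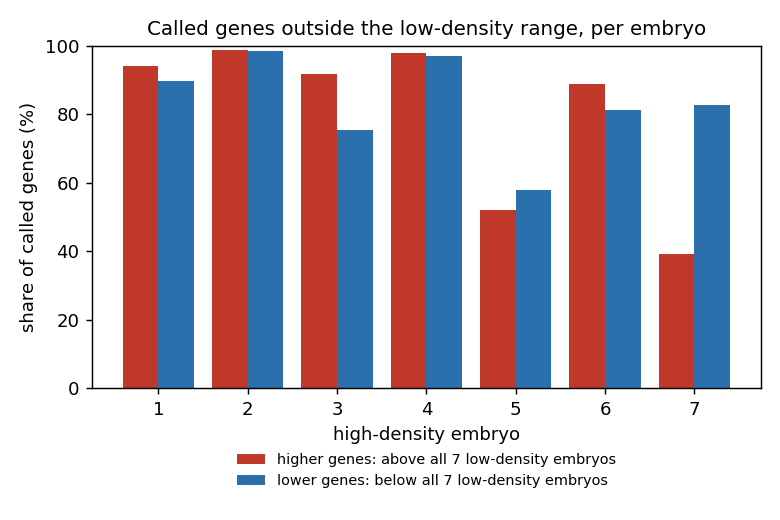
Share of called genes in percent (vertical axis) in which each of the 7 high-density embryos (horizontal axis) lay outside the range of the 7 low-density embryos. Red bars are the 546 higher genes and blue bars the 69 lower genes; the red bars run from 39.2% in embryo 7 to 98.9% in embryo 2.

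The number of called genes moved with single embryos. Without high-density embryo 2 it was 265, without embryo 4 it was 278, and without embryo 1 it was 386, but without embryo 5 it was 1158 and without embryo 7 it was 1211. Leaving out low-density embryos 2, 3, 4, 5 or 6 gave 250, 284, 396, 229 and 175 genes. Without both high-density embryos 2 and 4, 110 genes passed (98 higher, 12 lower), 105 of them among the 615, by the same edgeR test. In those 12 embryos DESeq2 called 473 genes and limma-voom 868. All 546 higher and all 69 lower genes kept the direction of their mean difference there, with medians of 1.02 and -0.63 log2 units, though they had been chosen with these embryos included. Over all 14 embryos DESeq2 called 1397 genes (1062 higher, 335 lower) and limma-voom 1390 (948 higher, 442 lower), so the share of called genes that was higher was 88.8% by edgeR, 76.0% by DESeq2 and 68.2% by limma-voom.

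**Figure D3:**
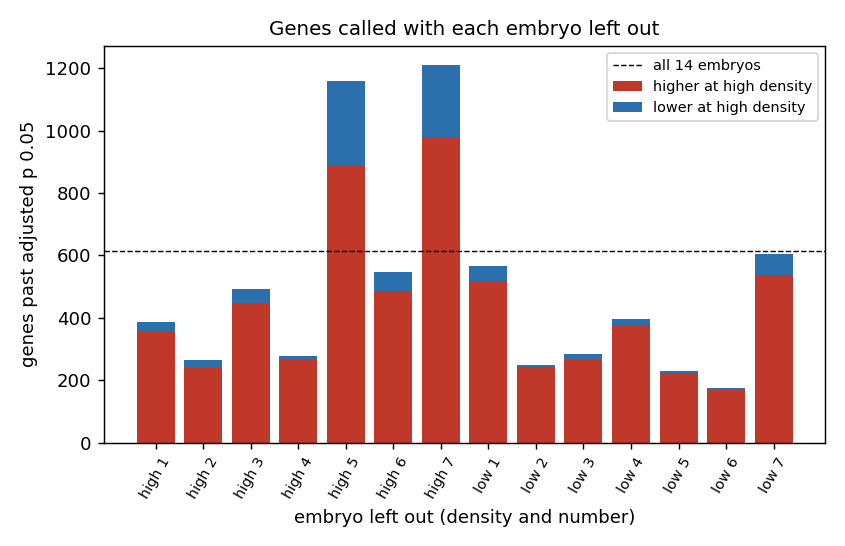
Number of genes past an adjusted p of 0.05 (edgeR, vertical axis) when the embryo named on the horizontal axis was left out, split into genes higher (red) and lower (blue) at high density. The dashed line marks the 615 genes found with all 14 embryos; bars run from 175 without low-density embryo 6 to 1211 without high-density embryo 7.

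The letter prefix of the sample code is the other label on which embryos split. Of 6 prefixes, 1 occurred in both densities, with 2 embryos of each. Among these 4 embryos alone, 135 genes passed (133 higher, 2 lower), of which 89 were among the 615. Among the 10 embryos of the other prefixes, 5 of each density, edgeR called 0 genes, with 1171 at an unadjusted p under 0.05, DESeq2 called 160 and limma-voom 1. With the prefix as a term in the edgeR model, 0 genes passed and 1411 had an unadjusted p under 0.05. This term leaves the comparison of densities to the 4 embryos of the shared prefix, as each other prefix occurs in 1 density. The median change of the 615 genes was 1.41 log2 units with a median SE of 0.33 over all embryos, 1.79 with an SE of 0.64 with the prefix term, and 1.25 with an SE of 0.41 in the 10 embryos (613 of the genes). These genes were called with all of these embryos, which favours a change in the called direction in each subset. The sizes of these changes are therefore no separate support for a difference with density.

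Taken over all tested genes, 23.1% of the squared distance between embryos lay between the density groups, where 7.69% is the mean over all assignments (exact permutation test, p = 0.0035). Without high-density embryos 2 and 4 the share was 15.9% (exact permutation p = 0.0442, the highest over 19 alternatives from 0.00175). The mean of 7.69% holds for the full set and is higher for fewer embryos. None of these alternatives took account of the code prefix. The first principal component held 52.4% of the variance of the 500 most variable genes and separated the groups, with scores of 19.0 ± 25.3 at high and -19.0 ± 12.1 at low density (SD, n = 7 each; exact two-sided permutation p = 0.0058, adjusted p = 0.0291 over 5 components). On it, 5 of 7 high-density embryos lay above all low-density ones. This separation did not pass without embryos 2 and 4 (adjusted p = 0.198, permutation test) or with a prior count of 0.5 (adjusted p = 0.108), in a range over 4 alternatives that began at 0.00874. Components 2 to 5 did not separate the densities, with exact permutation p-values of 0.774, 0.410, 0.620 and 0.218. Embryos lay 67.0 ± 20.1 log2 CPM units from their group's centroid at high density and 49.0 ± 10.6 at low density (SD, n = 7 each), a difference of 18.0 that did not pass the threshold (exact two-sided permutation p = 0.0554). Without high-density embryo 7 it was 10.1 (exact permutation p = 0.168) and without embryo 2 it was 13.1 (p = 0.156). It passed without high-density embryo 1 (19.8, exact permutation p = 0.0402), 3 (20.7, p = 0.0297) or 6 (21.2, p = 0.0204), or without low-density embryo 7 (23.0, p = 0.0152), and was 8.96 without high-density embryos 2 and 4 (p = 0.378).

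**Figure D4:**
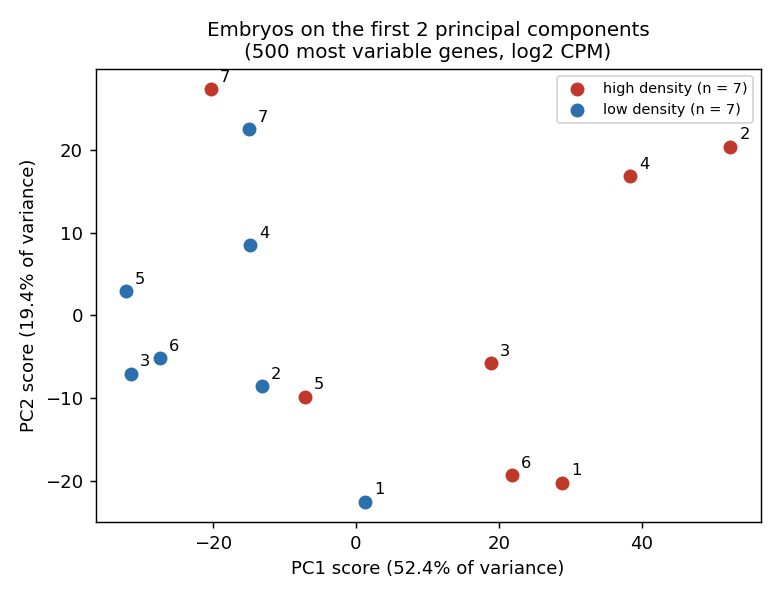
Scores of the 14 embryos on the first principal component (horizontal axis, 52.4% of variance) and on the second (vertical axis, 19.4% of variance) of log2 CPM of the 500 most variable genes. Numbers are embryo numbers within high density (red) and low density (blue); high-density embryos 2 and 4 have the highest PC1 scores, 52.4 and 38.4.

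Embryos 2 and 4 of the high-density group stood apart from the rest in their correlation with low-density embryos. By distance to the group's centroid, embryo 7 lay farthest (100.6), then embryo 2 (86.2), embryo 5 (67.5) and embryo 4 (65.3). The mean correlation of embryos 2 and 4 with the low-density embryos was 0.782 and 0.842, against 0.895 to 0.947 for the other 5 high-density embryos (Pearson's r across genes, which are not independent replicates). Relative to the mean of the other 12 embryos, 148 genes were at least 4-fold higher in both and 363 genes were at least 4-fold lower in both. Of the 148 higher genes 99 were among the 615 called, and of the 363 lower genes 0 were. In mean log2 CPM of the 148 genes, the other 5 high-density embryos and the 7 low-density embryos differed by 1.64, which did not pass the threshold after adjustment (0.96 ± 1.42, SD, n = 5, against -0.68 ± 0.70, SD, n = 7; exact two-sided permutation p = 0.0278, adjusted p = 0.0556 over both gene sets). Embryos 1, 3 and 6 lay above all low-density embryos, and embryos 5 (0.079) and 7 (-1.108) within their range. The 363 genes differed by -0.46 between the same embryos (-0.27 ± 0.36, SD, n = 5, against 0.19 ± 0.42, SD, n = 7; exact permutation p = 0.0833, adjusted p = 0.0833).

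**Figure D5:**
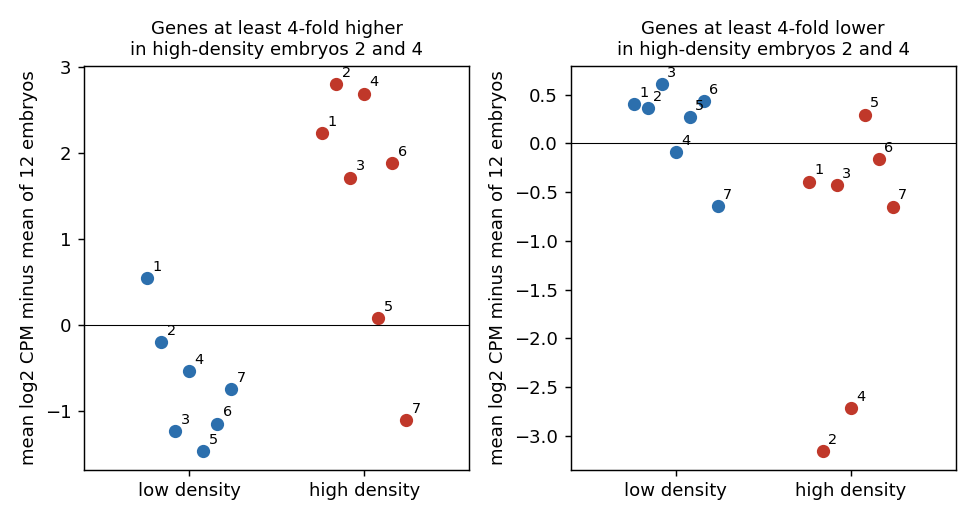
Mean log2 CPM of 148 genes at least 4-fold higher (left) and 363 genes at least 4-fold lower (right) in both high-density embryos 2 and 4, relative to the mean of the other 12 embryos (vertical axes), for each low-density (blue) and high-density (red) embryo, with its number. In the left panel high-density embryos 1, 3 and 6 stand at 2.23, 1.71 and 1.88, above all low-density embryos, while in the right panel embryos 2 and 4 stand alone at -3.16 and -2.72. The genes were picked by the values of embryos 2 and 4, which fixes the place of those embryos in both panels.

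One gene was the most abundant in 13 of the 14 libraries and the next most abundant in the remaining one. It took 4.40 ± 0.38% of counts at low density and 2.93 ± 1.28% at high density (SD, n = 7 each), a difference of -1.47 percentage points (exact two-sided permutation p = 0.0087, adjusted p = 0.0350 over 4 library measures). Without embryos 2 and 4, whose shares were 1.09% and 1.53%, the high-density share was 3.57 ± 0.78% (SD, n = 5) and the difference -0.83 percentage points (exact permutation p = 0.0366, not adjusted). In edgeR's test with TMM scaling the same gene had a log2 fold change of -0.53 ± 0.31 (SE) and did not pass (adjusted p = 0.296). The 10 most abundant genes together took 8.91 ± 0.49% at low and 7.86 ± 1.67% at high density (SD, n = 7 each; exact permutation p = 0.133, adjusted p = 0.266).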

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

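In this part, the tests of the code prefix, of splits that keep prefixes whole, of the gene set shared with the other high-density embryos and of a single admixed source were chosen after the results they bear on were seen. Leaving out high-density embryos 2 and 4 and thinning to equal totals were chosen after the data were seen, with the reading of each set before its own result. The prefix test replaced an earlier one, whose reading was set before its result, which compared the median change of the called genes in the 4 embryos of the shared prefix (1.64) with that in the other 10 (1.06). It used genes called with these same embryos, which fixed its outcome. It pointed the same way as its replacement.

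The first pattern is the 615 genes that differed with density: of 100 splits of the 14 embryos into 7 and 7, only the real 1 gave as many and the highest other gave 73, which argues against chance if embryos are independent, but of the 18 splits that keep single-density prefixes whole the real 1 gave 615 and the highest other 0 (edgeR; 106 to 1615 at an unadjusted p under 0.05), and 18 splits are too few for a share under 0.05. Depth as the whole cause is argued against by the 607 genes that passed when every library was thinned to one total. Whether the prefix is the whole cause was tested in the 4 embryos of the shared prefix. There, 1160 genes picked at an unadjusted p under 0.05 in the 10 embryos of other prefixes moved the same way by a median of 1.251 log2 units. The other splits of those 4 embryos gave 0.21 and 0.32 (edgeR calls 135, 0 and 0, with 1830, 110 and 34 at an unadjusted p under 0.05). The 698 genes picked without high-density embryo 2 moved by 0.98 in high-density embryo 6 alone. These values go against the prefix as the whole cause within those 4 embryos. They do not settle it, because 4 embryos allow too few splits for a share under 0.05 and genes are not independent replicates. How far high-density embryos 2 and 4 carry the calls stays open, because 110 genes passed without them and the called genes, chosen with them, kept medians of 1.02 and -0.63 log2 units in the other 5, while leaving out the other 20 pairs gave from 0 (embryos 1 and 4; 1860 at an unadjusted p under 0.05, edgeR) to 1824, with a median of 556.5 and 5 pairs lower. Breeding density, and whatever else differs between the mothers or places sampled, remains open and untested.

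The second pattern is that high-density embryos 2 and 4 stand apart, and depth is argued against, since at equal totals their mean correlations with low-density embryos were 0.774 and 0.8346 and those of the other 5 at least 0.893. Admixture of RNA from another tissue may add to it, but its test did not decide: genes that fell 4-fold in one of these embryos fell in the other with an SD up to 1.926 times that between low-density embryos, between the bounds of 1.5 and 3 set for it. Their median log2 change was -2.20 in embryo 4 (330 genes picked in embryo 2) and -3.33 in embryo 2 (212 genes picked in embryo 4). Dilution alone would need most of the RNA in both embryos to come from elsewhere for falls of this size. Whether the other 5 share the pattern stays open: the mean of the set higher in both differed by 1.641 log2 units between them and low density, with an exact permutation p of 0.0278 that did not pass after adjustment (0.0556), and embryos 5 and 7 lay within the low-density range. A test of one source mixed into more embryos did not decide either. Embryos 1, 3 and 6, picked because they rose, showed 0.501, 0.410 and 0.334 of the rise of embryo 2 in CPM, against -0.068 to 0.067 in single low-density embryos. Their shares of its fall were 0.413, 0.443 and 0.313 (smallest ratio of rise to fall 0.9259). In each of them the 95% intervals of rise and fall, from resampled genes, overlapped, as one source would give. But these shares of the fall, and that of high-density embryo 7, 0.536, lay within the low-density range of -0.357 to 0.560. Low-density embryo 7 alone set its upper end. The next value, 0.262 in low-density embryo 4, was below all of these shares. A change in the make-up of the brain itself, such as in developmental stage, could give the same values as admixture, and without gene names neither was tested against the other.

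The third pattern is the low number of genes detected in high-density embryo 7, 11308 against 12225 in the next lowest of its group. It was 11298 at equal totals, below the 11850 to 12366 of the other 13 embryos, so depth is argued against as the whole cause. No biological explanation was tested.

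For independent, normally distributed values, chance alone gives an outlying value in about 1 of 20 groups. CPM values are not logged and can be skewed, and some of these genes were picked for large changes, so that rate need not apply. Of the 40 groups of 7 values, 8 held one that lay far from the others, the number of genes detected included. High-density embryo 7 was the outlying sample for the less abundant H3.3 entry (461.9 CPM, next 315.4), for the histone H4 entry (23.95 CPM, next 11.8) and for the RPL9 entry (4410.5 CPM, next 2444.8). Low-density embryo 7 was outlying for the same H3.3 entry (511.2 CPM, next 354.3). For tree_swallow008761 high-density embryo 2 was outlying at 235.8 CPM (next 56.4), for tree_swallow005195 low-density embryo 1 at 11.1 CPM (next 2.21), and for tree_swallow000990 high-density embryo 6 at 4.63 CPM (next 2.59).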

How the results depend on the processing

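In this part, equal totals, the filter of 5 CPM, the covariates from pairs of genes and leaving out high-density embryos 2 and 4, or 2, 4 and 7, were chosen after the data were seen. The count of 615 genes stayed within 1.5 times with RLE (629) and upper-quartile factors (652), without the expression filter (609), with a filter of 1 CPM in 7 embryos, meant to be stricter but keeping more genes (661 of 11328), with one of 5 CPM in 7 embryos (549 of 9454, 495 among the 615) and at equal totals (607). It rose to 1397 with DESeq2, 1390 with limma-voom and 1315 at an adjusted p under 0.1. It fell to 135 within the shared code prefix, to 110 without high-density embryos 2 and 4 and to 392 without embryos 2, 4 and 7, where 309 were among the 615. In edgeR, 0 genes passed with the prefix as a term (1411 at an unadjusted p under 0.05), without the shared prefix (1171; DESeq2 160, limma-voom 1) and with 1 surrogate variable (843). With the prefix term the median change of the 615 genes was 1.79 log2 units against 1.41, and its SE went from 0.33 to 0.64. This change rests on the 4 embryos of the shared prefix, since each other prefix occurs in 1 density. The 615 genes were called with these embryos included, which favours such a change. With the surrogate variable the change itself was 0.82. This variable ran from -0.613 to 0.204 at high density, lowest in embryos 2 and 4, and from -0.141 to 0.297 at low density. The fit cannot fully separate it from density. Expression of 2 genes that fell into 2 levels was used as a covariate. With a first pair, both of them called for density, 0 genes passed (663 unadjusted). This pair was higher in 5 high-density embryos (1, 2, 3, 4 and 6) and in 1 low-density embryo (1). It largely followed density, so the fit cannot separate the pair from density, and its 0 says little about the calls. With a second pair, higher in high-density embryos 3 and 7 and low-density embryos 3, 4 and 6, 303 genes passed, of which 300 were among the 615. Leaving out one embryo gave 175 to 1211 genes. The cause of these changes was not tested. The whole-transcriptome share passed in all 19 alternatives run. The settings that left 0 genes in edgeR, with the prefix as a term, without the shared prefix and with a surrogate variable, were not run for it. The separation on the first component, 1.39 SD, was 1.19 SD with a prior count of 0.5 (adjusted p = 0.108) and 0.93 SD without embryos 2 and 4 (adjusted p = 0.198), neither past the threshold. The difference in spread ranged from 10.1 to 23.0 with one embryo left out and passed without high-density embryos 1, 3 or 6 or low-density embryo 7. At this depth and spread, simulated changes of 1 log2 unit, drawn independently for each gene, were recovered in 46 of 100 genes. Alternatives for gene lists, list scores and sex-chromosome covariates were not run, for want of gene names.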

Other observations

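These divisions were looked for after the data were seen, and no test was made between them. Some genes took 2 separate levels among the embryos. Of the tested genes, 13 had a gap of at least 2 log2 units that was wider than the range on either side, with 3 or more embryos on each side, and these genes made 11 different divisions of the embryos. One division was shared by 2 genes, the second pair used as a covariate above. It put high-density embryos 3 and 7 and low-density embryos 3, 4 and 6 above the other 9 embryos, with gaps of 2.43 and 2.90 log2 units. Over all tested genes, 22 lay entirely above and 98 entirely below in these 5 embryos. Chance gives 5.38 each way for a division fixed beforehand, which this one was not. Neither of the 2 genes was called for density. The sex of the embryos is not given in the labels used here, so it could not be compared with this division.

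Another division, again shared by 2 genes, was that of the first pair used as a covariate. It put high-density embryos 1, 2, 3, 4 and 6 and low-density embryo 1 above the other 8 embryos. Its gaps were 2.28 and 2.56 log2 units, and both of its genes were among the 615.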
